A study of Homo sapiens with 11 samples.

How the data were processed

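HepG2 cells, an established line from a human hepatocellular carcinoma, were given fresh medium with obacunone or vehicle, per the labels' protocols, and total RNA was converted to biotin-labelled cRNA for Illumina bead arrays. The labels put 6 arrays in the vehicle group (0, 0.5, 1, 3, 6 and 12 h) and 5 in the obacunone group (0.5, 1, 3, 6 and 12 h), with 1 array for each agent and time.

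A table of bead intensity values that had not been normalized was deposited, with a detection p-value after each intensity column per the file headers. Its 34689 rows have intensities on a linear scale that still hold the background. For 27385 rows the detection p-values could be read as steps of 1 over 770, as for a single probe ranked against 770 negative controls. For the other 7304 they could not, and these rows were taken as means over several probes of a gene, which was not tested. The authors also deposited log2 values for the same rows. Every column of these has a median of 7.4365, and they differ by at most 0.00191 from the quantile-normalized log2 of the intensities, so they are quantile normalized without background correction, with their scale and centring settled by that comparison and no ratio or direction involved. The scanner software and its version are not given in the sources used here.

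Background was corrected with the normexp model of limma, with negative controls inferred from the detection p-values of the single-probe rows, an offset of 16 was added, and the arrays were quantile normalized and taken to log2. R 4.3.3 and limma 3.58.1 were used. Rows with a detection p-value under 0.05 on at least 3 of the 11 arrays were kept (15513 rows). Of the rows with a mean intensity above 300, 258 failed this filter, all of them rows taken as means over several probes. A high combined p where a bright and a dim probe are averaged may be the reason, which was not tested. Rows were named through a platform annotation and their symbols updated through gene identifiers in a table of RefSeq genes of GRCh38, which was used for names alone. Of all rows, 20701 had 1 symbol (20675 of them matched in that table), 8 had several and 13980 had no name here. Of the kept rows, 11007 had 1 symbol and 4506 had none. For each gene, the row with the highest mean over all arrays was used, which left 10719 genes. ATF3 is on the array but failed the filter.

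Comparisons were fitted with lmFit and eBayes of limma on log2 values, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The mean effect of obacunone over 5 times was fitted on the 10 arrays of the 5 shared times with time as a block (4 residual degrees of freedom). A second fit on the same arrays gave 1 effect for the early times (0.5 and 1 h) and 1 for the late times (3, 6 and 12 h), and their difference (3 residual degrees of freedom). The vehicle trend was the slope on log2(time + 1) over the 6 vehicle arrays (4 residual degrees of freedom). Time is the pairing of the arrays by design, and no other number pairs them. At single times only differences are given, over genes with a detection p-value under 0.05 on at least 1 of both arrays. A gene without such a p-value on any array of a group has only a bound there: the bright group's mean is set against the higher of the dim probe's own value and the lowest detected value on each array, and given as at least that fold. Errors are standard errors of the moderated fit.

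Gene lists (39, with 741 genes, of which 682 had a named row and 546 were tested) were tested with camera in limma with a preset correlation of 0.01 and, beside it, an estimated correlation, where at least 5 members were tested, which held for 36 lists. The estimate rests on the few residual degrees of freedom of each fit, so a pass with it is hard to reach. No list passed with it in any comparison, and a failure there does not show that a list is unchanged. Each list's median at a time was also ranked among 10000 random lists of the same size matched on mean expression. Genes of a random list need not vary together as those of a fixed list may, so a percentile is not a test. Some genes, 22 of those tested, belong to more than 1 list. The lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes, for each tested effect, the 10 highest and 10 lowest effects among passing genes with one sign in every pair, or, where fewer than 5 pass, the 5 highest and 5 lowest among the 50 smallest p-values, reported as not passing, and this second part applied throughout (for the vehicle slope, 6 in place of 10). It also takes the 5 highest and 5 lowest differences at each time among genes detected on both arrays, up to 4 members of each list by size of the late effect, and 10 genes named in advance. Further list members that passed when adjusted over their list alone were named after their values were seen, as were TXNRD1, SLC7A11 and FTL.

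The fits were tested on simulated data with the real gene means, time effects and spread, in which 200 of 10719 genes were changed at 3 to 12 h. For the late effect, 70.1% of genes changed 2-fold, 97% of those changed 4-fold and 19.4% of those changed 1.41-fold were called in the right direction, with 7 unchanged genes called. The fit of the mean effect over all shared times called 0 of the 200 changed genes, those changed 4-fold included, and 0 unchanged genes. A list of 18 genes shifted by 0.4 passed and 0 of 35 other lists did. The simulated noise was drawn independently for each gene. The simulation therefore cannot show how often lists pass wrongly where genes vary together. Each simulated change had 1 size at 3, 6 and 12 h, and each gene's spread was its own estimate from 3 residual degrees of freedom. Real differences could change over these times, as for SRXN1 (0.77, 1.26 and 1.89), so the shares recovered need not hold for real genes. The vehicle slope recovered 82.1% of genes with a slope of 0.5 and 46.3% of those with a slope of 0.25, with 11 unchanged genes called.

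Alternatives covered the background correction, the normalization, the authors' log2 values, the detection filter, the row used per gene, the variance prior, the time block, the division into early and late, each pair left out and the correlation within lists. An intensity filter, a test of all rows named or not, and the list test on the late-minus-early difference were added after seeing the data. The slide of each array is not given in the sources used here, so it was not used as a block. Kept rows without a name were tested in the alternative with all rows and in no other comparison.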

Results

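Gene expression was measured in HepG2, a human liver cancer cell line, after exposure to obacunone, a triterpenoid of the limonoid class found in citrus fruit. The purpose given for the series is to follow how obacunone regulates genes over time. RNA was collected at 0.5, 1, 3, 6 and 12 h from cells exposed to 100 uM obacunone, and at 0, 0.5, 1, 3, 6 and 12 h from cells given the vehicle, 0.1% DMSO. Each of the 11 combinations of agent and time was measured on 1 Illumina bead array, so no time point had a replicate. The 5 time-matched pairs of an obacunone and a vehicle array are the repeats of the comparison, and their number limits the precision. The labels do not say that dishes were handled in separate experiments, so the p-values measure the spread between these arrays, part of which may be technical and part a real change of the effect with time. The arrays had median intensities between 159.1 and 179.8, and 13365 to 14336 of 34689 rows (38.5% to 41.3%) gave a detection p under 0.05. On the first principal component, which held 27.4% of the variance of the 10719 genes tested, the obacunone array of 12 h lay at 28.9, the obacunone array of 6 h at 11.7 and the vehicle array of 12 h at 6.3, with the other 8 arrays between -12.9 and 1.2. On the second component (13.7%), the vehicle array of 1 h lay apart at -18.2, with the others between -7.2 and 10.2.

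With a preset correlation in the list test, genes that defend against electrophiles and oxidants had the smallest adjusted p at 3 to 12 h. With an estimated correlation no list passed, and the endoplasmic reticulum list had the smallest adjusted p (0.356). Targets of the transcription factor NRF2 rose as a group: 24 of the 25 list genes measured had a late effect (the mean difference from vehicle over 3, 6 and 12 h) above 0, and 20 were higher at each of the 3 times. The list passed the set test with a preset correlation (adjusted p = 3.53e-15) and not with an estimated correlation (adjusted p = 0.441). SRXN1, which encodes the enzyme that repairs overoxidised peroxiredoxins, had a late effect of 2.47-fold (SE 0.19 on the log2 scale, n = 3 pairs). HMOX1, encoding the heme-degrading heme oxygenase 1, had an effect of 1.20 ± 0.18 (2.30-fold), and GCLM, a subunit of the enzyme that starts glutathione synthesis, 1.11 ± 0.19 (2.17-fold). GCLC, the catalytic subunit of the same enzyme, was not above background on the late vehicle arrays and was at least 2.36-fold higher with obacunone. TXNRD1, encoding thioredoxin reductase, had an effect of 0.96 ± 0.20 and SLC7A11, encoding the cystine transporter, 0.80 ± 0.24. The median difference of the list grew from 0.13 at 3 h to 0.27 at 6 h and 0.73 at 12 h, after 0.09 at 0.5 h and -0.01 at 1 h. It stood at percentile 100 of 10000 random lists matched on expression at each of 3, 6 and 12 h. Such a percentile on 1 array per agent is weak support. The fatty acid and triglyceride synthesis list also stood at percentile 100 at 3 h and did not pass the late set test (adjusted p = 0.115).

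Adjusted over the list alone, 10 of the 25 NRF2 targets passed, all upward, while over all genes tested none of the 25 did. The 10 included MAFG (0.51), UGDH (0.57), AKR1B10 (0.71) and ABCC2 (0.88). FTL, the ferritin light chain gene, was the member with a negative effect, at -0.01. The mean difference of the list was above 0 in 5 of 5 pairs, and the two-sided exact p from exchanging signs was 0.0625, the smallest that 5 pairs allow. The heat shock, PPAR gamma, interferon (below 0) and cAMP lists had the same exact p of 0.0625, so this value is not particular to NRF2 targets.

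**Figure D1:**
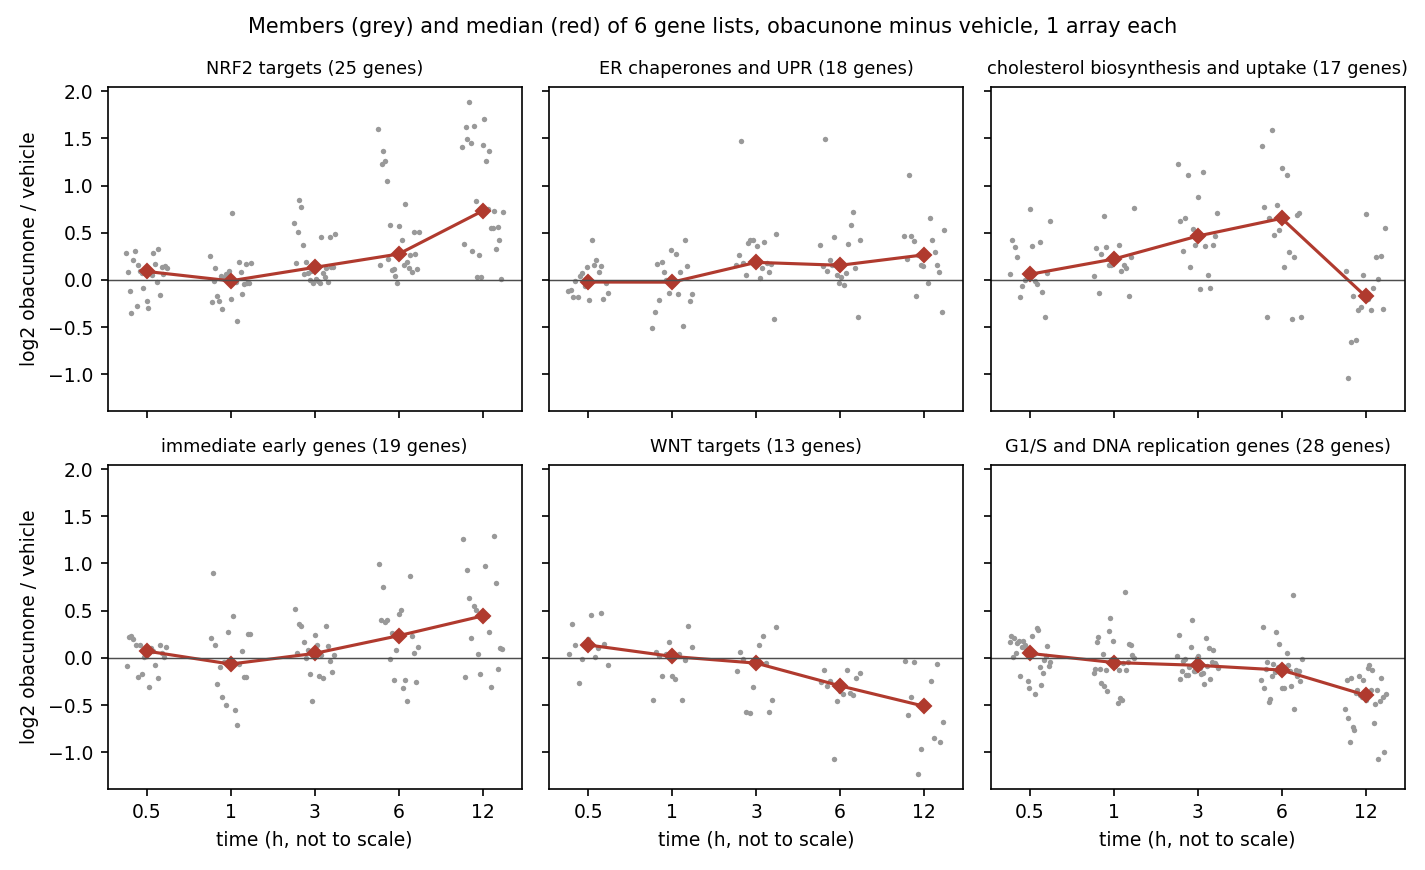
Difference between the obacunone and the vehicle array (log2, vertical axis) at each time (h, horizontal axis, not to scale) for the measured members of 6 gene lists, with 1 grey point per gene and the list median in red. The median of the NRF2 list climbs to 0.73 at 12 h, that of the cholesterol list peaks at 0.65 at 6 h and stands at -0.17 at 12 h, and that of the WNT list falls to -0.51 at 12 h.

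Genes of the endoplasmic reticulum's protein-folding machinery also rose as a group at 3 to 12 h, with 16 of 18 members above 0 (adjusted p = 1.08e-06, and adjusted p = 0.356 with an estimated correlation). Its leading member was DNAJB9, encoding a co-chaperone of the endoplasmic reticulum, at 1.36 ± 0.13 (SE, n = 3 pairs, 2.56-fold). Adjusted over the list alone, 4 members passed upward, which were DNAJB9, SELENOS (0.48), HYOU1 (0.40) and MANF (0.38), and 1 passed downward. The latter was XBP1, itself a transcription factor of the unfolded protein response, at -0.38 ± 0.11, and its total transcript level was measured here, not its splicing. Over all genes tested, DNAJB9 was the only member of any list that passed at the late times. Targets of ATF4, the factor that acts in the integrated stress response, had 20 of 24 members above 0 and a median of 0.18 (adjusted p = 0.000351, and 0.378 as the adjusted p with an estimated correlation). Their largest effects were those of DDIT3 (0.62 ± 0.16), STC2 (0.45 ± 0.12) and PPP1R15A (0.39 ± 0.13), none of which passed, and no member passed when adjusted over the list alone. Heat shock genes had 15 of 17 members above 0 and a median of 0.16 (adjusted p = 0.000667, and adjusted p = 0.441 with an estimated correlation), with no member passing when adjusted over the list alone. HSPA1A had differences of 1.66 at 6 h and 0.19 at 12 h. Its near-identical copy HSPA1B, whose signal its probe may share, had 0.74 and -0.11.

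The cholesterol synthesis and uptake list rose at 3 to 12 h in the set test, with 14 of 17 members above 0 and a median of 0.29 (adjusted p = 0.000107, and adjusted p = 0.495 with an estimated correlation). Its course differed from that of the NRF2 list, with medians of 0.46 at 3 h, 0.65 at 6 h and -0.17 at 12 h, at percentiles 100, 100 and 6.69 of random lists. HMGCS1, which encodes the synthase ahead of the step controlled by HMG-CoA reductase, had differences of 1.23, 1.42 and 0.09 at 3, 6 and 12 h. IDI1, an isomerase of the isoprenoid branch, had 1.11 at 3 h and 1.59 at 6 h and was lower than vehicle at 12 h. MSMO1, a sterol demethylation enzyme, had 1.14, 1.11 and -0.32. CYP51A1, lanosterol demethylase, was higher in all 5 pairs and had a late effect of 0.92 ± 0.14 (adjusted p = 0.0964). Adjusted over the list alone, 3 members passed, all upward, which were CYP51A1, HMGCS1 and SC5D (0.44). CYP1A1, a xenobiotic-metabolising enzyme and target of the aryl hydrocarbon receptor, had 2.37 at 3 h and 2.63 at 6 h. At 12 h it was not above background on either array, so a ratio there has no meaning. The late effect of CYP1A1 takes in that 12 h difference all the same. The other 4 measured targets of that receptor had late effects between 0.04 and 0.24, among them NQO1, which the NRF2 list also holds. The mean late effect of the 5 was 0.44, and 2 of them were higher at each of the 3 late times. The receptor's list was not tested without CYP1A1. With all 5 above 0 and a median of 0.16, this list passed at an adjusted p = 0.0451, and not with an estimated correlation (adjusted p = 0.441). That call was lost without the 0.5 h pair or the 1 h pair (adjusted p = 0.0538 in each case), the 3 h pair (0.0541) or the 12 h pair (0.0657). The list's median stayed at 0.16 without an early pair, and was 0.25 without the 3 h pair and 0.13 without the 12 h pair.

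Immediate early genes, transcription factors and regulators that respond within minutes to growth signals, rose as a group at the late times, with 13 of 19 members above 0 and a median of 0.18 (adjusted p = 0.000667, and adjusted p = 0.495 with an estimated correlation). By time, the list's median was 0.07 at 0.5 h, -0.07 at 1 h, 0.05 at 3 h (percentile 87.62 of random lists), 0.23 at 6 h and 0.44 at 12 h. FOS had differences of 0.52 at 3 h and 0.99 at 6 h and a late effect of 0.92 ± 0.15, against -0.09 at 0.5 h and 0.21 at 1 h. ZFP36, which promotes mRNA decay, had a late effect of 0.83 ± 0.17 and FOSL1 0.68 ± 0.13. Adjusted over the list alone, 5 members passed upward (FOS, FOSL1, ZFP36, JUN and MYC) and 1 downward (CCN2, at -0.33). Autophagy and lysosome genes had 15 of 22 members above 0 and a median of 0.11 (adjusted p = 0.0182, and adjusted p = 0.441 with an estimated correlation), led by GLA (0.59 ± 0.18) and GABARAPL1 (0.55 ± 0.17), with no member passing when adjusted over the list alone. Without the 12 h pair, this list's adjusted p was 0.0501 and its median 0.12.

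A set of 3 groups of genes fell at 3 to 12 h. All 13 measured WNT targets had late effects below 0, with a median of -0.29 (adjusted p = 1.5e-05, and adjusted p = 0.441 with an estimated correlation), and 9 were lower at each of the 3 times. By time, the WNT median was 0.14 at 0.5 h, 0.01 at 1 h, -0.06 at 3 h, -0.30 at 6 h and -0.51 at 12 h. At 3 h it stood at percentile 22.65 of random lists, so the fall lay mainly at 6 and 12 h. DKK1, a secreted WNT antagonist that the pathway induces, had -0.96 ± 0.14 (SE, n = 3 pairs), SP5 -0.58 ± 0.14 and APCDD1 -0.52 ± 0.14, and these 3 passed when adjusted over the list alone. Of the genes of the G1/S transition and DNA replication, 25 of 28 were below 0, with a median of -0.19 (adjusted p = 5.03e-05, and adjusted p = 0.556 with an estimated correlation). E2F2 had -0.61 ± 0.16, MCM5, a subunit of the replicative helicase, -0.46 ± 0.13, and TK1 -0.44 ± 0.17, and no member passed when adjusted over the list alone. Their median stood at -0.08 at 3 h, -0.13 at 6 h and -0.40 at 12 h, and without the 12 h pair the call was lost (adjusted p = 0.0724, median -0.10). The NF-kappa B and inflammatory list had 8 of 11 members below 0 and a median of -0.20 (adjusted p = 0.0456, and adjusted p = 0.441 with an estimated correlation). TNFAIP3 at -0.66 ± 0.16 and NFKBIA, the inhibitor of NF-kappa B, at -0.36 ± 0.11 passed downward when adjusted over the list alone. That call was lost without background correction (adjusted p = 0.0561), without the 3 h pair (adjusted p = 0.052) and without the 6 h pair (adjusted p = 0.148). It was also lost with each other filter, at an adjusted p of 0.0663 with none, 0.0529 among genes detected on all 11 arrays and 0.0604 with an intensity filter. The list's median was then -0.11 without background correction and -0.09 with no filter, and in the other 4 cases it stayed between -0.23 and -0.18.

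Gene by gene, the late effect passed the threshold for 1 of 10719 genes, DNAJB9, upward (adjusted p = 0.0277, higher in 3 of 3 late pairs). At an unadjusted p under 0.05 there were 1341 genes, 584 higher and 757 lower, where chance gives about 536, and 13 genes had an adjusted p under 0.1, 11 of them higher. Among the 50 smallest p-values, the highest effect was that of NMRAL2P, at 1.86 ± 0.29 (adjusted p = 0.111), which did not pass. The lowest, none of which passed, were NFE2, a hematopoietic transcription factor, at -0.97 ± 0.18, DKK1, PROX1, a homeobox factor of liver and lymphatic development, at -0.86 ± 0.13, IL22RA1, an interleukin 22 receptor subunit, at -0.83 ± 0.16 and TIGD2 at -0.74 ± 0.14, with adjusted p-values from 0.0964 to 0.123. The count depended on the setting: 58 genes passed without background correction (41 higher and 17 lower) and 72 with a variance prior that follows expression (48 higher and 24 lower). There were 19 among genes detected on all 11 arrays (15 higher and 4 lower) and 7 with median centring (5 higher and 2 lower). It was 9 without the 3 h pair and 0 without the 0.5 h, the 1 h or the 6 h pair, and without the 12 h pair DNAJB9 did not pass (adjusted p = 0.057).

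**Figure D2:**
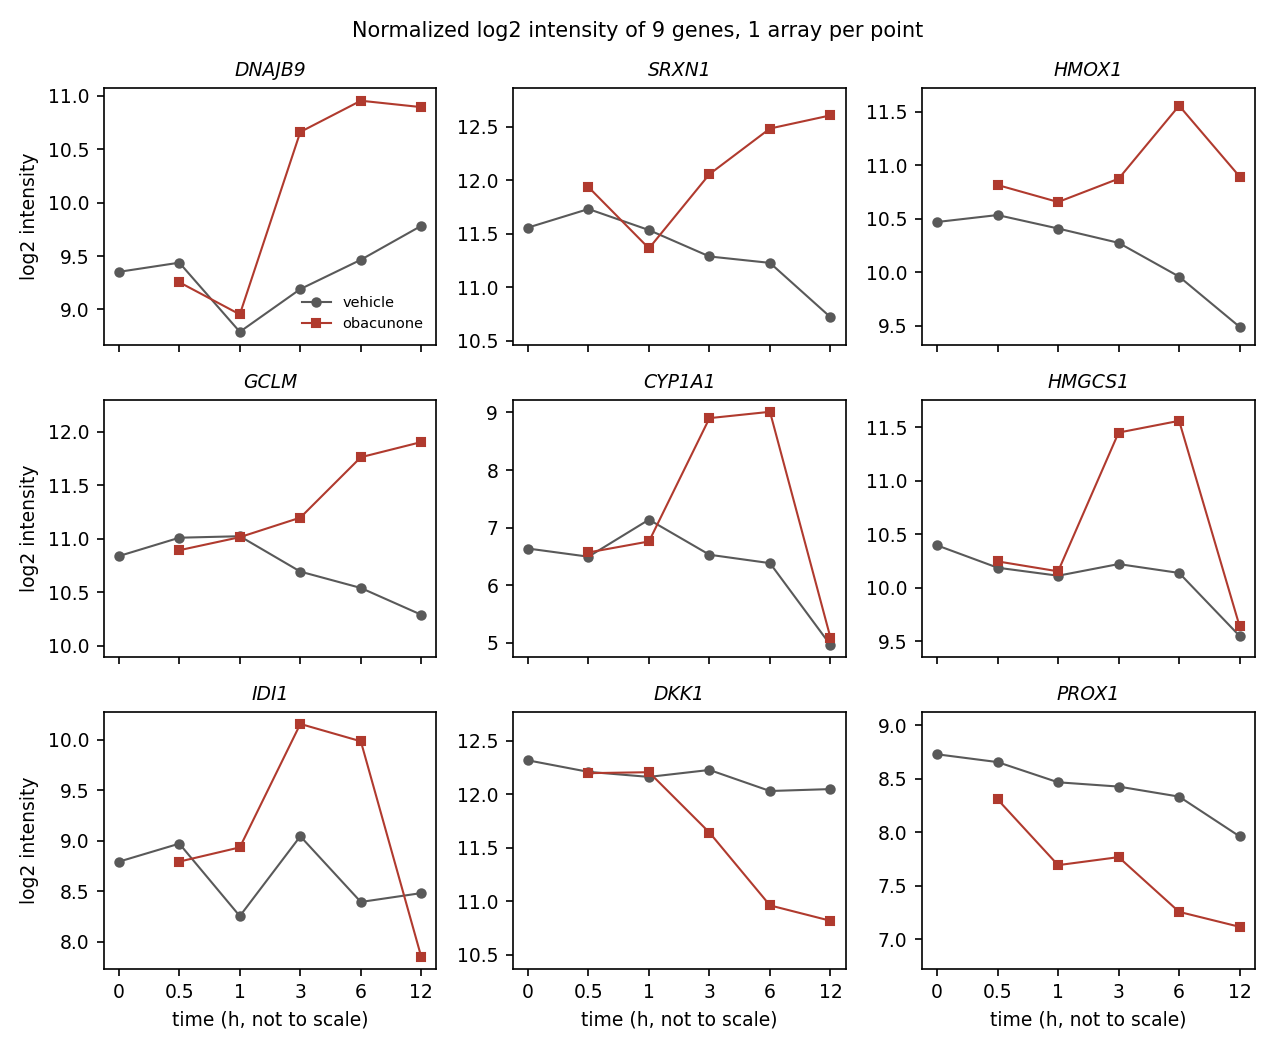
Normalized log2 intensity (vertical axis, scaled for each gene) at each time (h, horizontal axis, not to scale) for 9 genes on the 6 vehicle arrays (grey circles) and the 5 obacunone arrays (red squares), 1 array per point and so without error bars. HMOX1 stands at 9.49 on the vehicle array and 10.89 on the obacunone array at 12 h, and CYP1A1 at 6.38 and 9.01 at 6 h. At 12 h CYP1A1 is at background on both arrays.

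Over all 5 times, the question was which genes differed from vehicle whatever the time. The simulated data held changes at the late times alone, and this fit called 0 of those 200 genes. A lack of passing genes here is thus no evidence that late changes are absent. Among the 50 smallest p-values, the highest effects were those of HMOX1 (0.83 ± 0.20, SE, n = 5 pairs), CYP51A1 (0.76 ± 0.12), ADI1, an enzyme of the methionine salvage pathway (0.61 ± 0.13), the deubiquitinase gene USP12 (0.60 ± 0.11) and ATAD2B (0.56 ± 0.13). The lowest among the same 50 were PROX1 (-0.74 ± 0.11), the small nucleolar RNA SNORD91A (-0.65 ± 0.13), LEAP2, a liver-expressed peptide (-0.61 ± 0.14), NFKBIZ, a regulator of NF-kappa B (-0.57 ± 0.09) and TNFAIP8L1 (-0.55 ± 0.13). All had one sign in 5 of 5 pairs except ATAD2B, at -0.01 in the 12 h pair. None of them passed: 0 genes had an adjusted p under 0.05 in limma's moderated test (the smallest was 0.313), and 780 had an unadjusted p under 0.05 where chance gives about 536.

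As groups, 12 lists passed for the mean over 5 times, 8 upward and 4 downward, and 9 of them were among the 11 that passed at the late times. The NRF2 list had the smallest adjusted p (4.85e-12, median 0.26), followed by the cholesterol list (1.04e-06, median 0.23) and the endoplasmic reticulum list (0.000134, median 0.13). With an estimated correlation no list passed (adjusted p = 0.437 for these 3 and for the PPAR gamma and interferon lists, and 0.571 for the G2/M list). The 3 that passed here and not at the late times were PPAR gamma and adipocyte genes, higher (median 0.18, adjusted p = 0.0183), G2/M and mitosis genes, lower (median -0.08, adjusted p = 0.0256), and interferon-stimulated genes, lower (median -0.14, adjusted p = 0.0263). Of their members, 6 of 8 were above 0 in the PPAR gamma list, 24 of 30 below 0 in the G2/M list and 9 of 12 below 0 in the interferon list. Named members were ACSL1 (0.35 ± 0.14) and, opposite to its list, CEBPA (-0.27 ± 0.17), TOP2A (-0.31 ± 0.10) and IFIT1 (-0.33 ± 0.13). Adjusted over the list alone, none of the 3 lists had a passing member for the mean effect. Without the 12 h pair 4 lists passed, all upward: NRF2, endoplasmic reticulum, heat shock and cholesterol. The calls of the 3 added lists were then lost (adjusted p = 0.0565 for PPAR gamma, 0.567 for G2/M and 0.0604 for interferon). The PPAR gamma median stayed at 0.17, while those of G2/M and interferon shrank to -0.04 and -0.09. The 3 calls were also lost without the 1 h pair (adjusted p = 0.124, 0.157 and 0.0952), with medians still at 0.13, -0.06 and -0.11, and those of PPAR gamma and interferon without the 0.5 h pair (adjusted p = 0.0506 and 0.0758, medians 0.15 and -0.08). The interferon call was lost with no detection filter (median -0.05, adjusted p = 0.143) and the PPAR gamma call among genes detected on all 11 arrays, where its median stayed at 0.17 (adjusted p = 0.118). Without the time block, the G2/M call was lost with 5 vehicle arrays (adjusted p = 0.119, median -0.08) and the PPAR gamma call with 6 (adjusted p = 0.0768, median 0.13).

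At 0.5 and 1 h, no gene passed in limma's moderated test (the smallest adjusted p was 0.863), and 566 genes had an unadjusted p under 0.05 where chance gives about 536. For the difference between the late and the early effects, which tests whether the response changed with time, no gene passed either (smallest adjusted p 0.48, with 973 genes at an unadjusted p under 0.05). The 5 highest differences among the 50 smallest p-values were SEL1L3 (1.49), CYP4F11, a fatty acid hydroxylase (1.41), DNAJB9 (1.37), GCLC, which was not above background on the late vehicle arrays, and SRXN1 (1.29). The 5 lowest were GMPR, a purine nucleotide enzyme whose probe was not above background on the late obacunone arrays, NFE2 (-1.20), STK11, the kinase LKB1 (-1.13), C17orf99 (-1.12) and ASRGL1 (-1.07), with adjusted p-values between 0.48 and 0.495. Without background correction 1 gene passed, upward, and so did 1 with the expression-dependent variance prior.

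At single times, where each difference rests on 1 array per agent and has no replicate check, the number of genes at least 2-fold apart was 22 at 0.5 h (8 higher and 14 lower), 33 at 1 h (19 and 14), 18 at 3 h (14 and 4), 50 at 6 h (35 and 15) and 116 at 12 h (57 and 59). The highest at 0.5 h were ERV3-1 (2.11-fold) and F2, encoding prothrombin (1.05), and the lowest CREB3 (-1.43). The extremes at 1 h were NRTN, a neurotrophic factor (1.25), and ACTR8 (-1.28), with signs that varied at the other times. At 3 h the highest were CYP1A1 (2.37), DNAJB9 (1.47), HMGCS1 (1.23), NMRAL2P (1.18) and LPIN1, a phosphatidate phosphatase (1.16), and the lowest IL22RA1 (-1.27). At 6 h the highest were CYP1A1 (2.63), HSPA1A (1.66), HMOX1 (1.60), IDI1 (1.59) and DNAJB9 (1.49), and the lowest MIR635 (-1.36), B3GAT3 (-1.25), SNORD91A (-1.23) and SOWAHA (-1.16). At 12 h the highest were NMRAL2P (3.00), AKR1B15 (4.84-fold, a near-identical relative of AKR1B10, so the probe may measure both), SRXN1 (1.89), GPAT3, an enzyme of glycerolipid synthesis (1.79), and SEL1L3 (1.76). The lowest at 12 h were CYGB, encoding cytoglobin (0.282 of the vehicle level), ARSI (-1.71), SOWAHA (-1.70), CYSRT1 (-1.47) and HOXD1 (-1.45).

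Differences at separate late times, which share no array, went together across genes, with Pearson's r of 0.20 for 3 and 6 h, 0.22 for 3 and 12 h and 0.31 for 6 and 12 h, while the 7 pairs with an early time gave -0.20 to 0.08. These are correlations across 10719 genes, which are not independent replicates. Of the genes 2-fold higher, 11 were shared between 6 and 12 h where independent lists would share 0.18, 6 between 3 and 6 h where 0.046 would be, and 2 between 3 and 12 h where 0.073 would be. Of the genes 2-fold lower, 4 were shared between 6 and 12 h (0.09 if independent), 0 between 3 and 6 h and 0 between 3 and 12 h. Without background correction, the differences of 39 of the 50 genes picked at single times changed by more than the standard deviation of all differences at that time. The counts depended on the scaling: without background correction they were 0, 1, 4, 10 and 23 from 0.5 to 12 h, with 4 higher and 0 lower at 3 h, 9 and 1 at 6 h, and 18 and 5 at 12 h. Median centring gave 12 higher and 9 lower at 3 h and 40 higher and 143 lower at 12 h, because it moved the median difference of all genes to -0.16 at 12 h, from -0.02 with quantile normalization. It also moved the share of genes with a late effect above 0 from 46.7% to 32.7%, and effects are stated here relative to the quantile-normalized values.

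**Figure D3:**
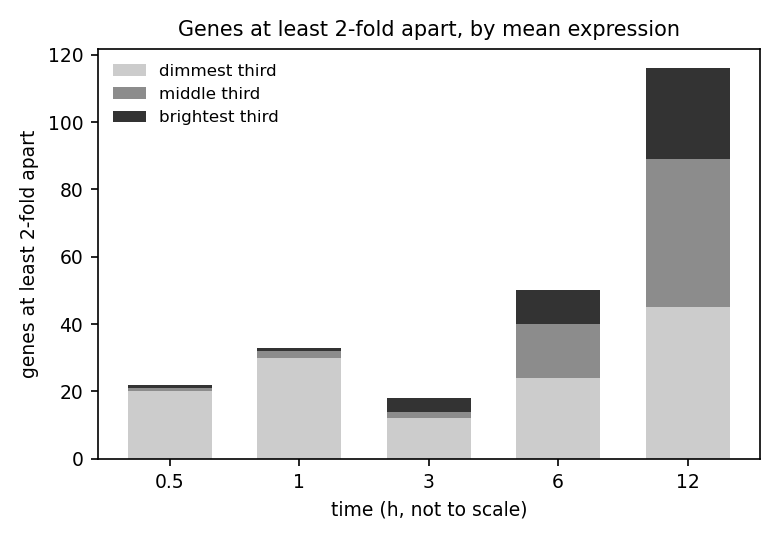
Number of genes at least 2-fold apart between the obacunone and the vehicle array (vertical axis, stacked bars) at each time (h, horizontal axis, not to scale), divided by mean expression over the 11 arrays. At 0.5 h 20 of 22 such genes and at 1 h 30 of 33 lie in the dimmest group, against 45 of 116 at 12 h.

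Time in fresh medium with vehicle alone was described by the slope of expression on log2(time + 1) over the 6 vehicle arrays. The highest slopes among the 50 smallest p-values were those of ANGPTL8, a hepatokine induced by feeding (0.41 ± 0.07, SE, n = 6 arrays), SOX8 (0.33 ± 0.08), HOXD1 (0.32 ± 0.08), TERC, the telomerase RNA (0.30 ± 0.07), and SLC1A2, a glutamate transporter (0.30 ± 0.06). The lowest were SGK1, a kinase induced by serum and glucocorticoids (-0.32 ± 0.05), TNS1 (-0.31 ± 0.07), GBP1, an interferon-inducible GTPase (-0.31 ± 0.06), THBS1 (-0.28 ± 0.06) and HMOX1 (-0.27 ± 0.05). None passed in limma's moderated test (smallest adjusted p 0.324, with 777 genes at an unadjusted p under 0.05), and 1 gene passed, downward, without background correction. HMOX1 went from 10.53 at 0.5 h to 9.49 at 12 h on the vehicle arrays and from 10.82 to 10.89 on the obacunone arrays, so that part of its difference at 12 h lies in the level of the vehicle array.

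The other 25 lists tested did not pass at the late times. Among lists of metabolism, the late median and adjusted p were 0.13 and 0.0572 for metallothioneins, 0.10 and 0.115 for fatty acid and triglyceride synthesis, -0.06 and 0.44 for fatty acid oxidation and PPAR alpha targets, 0.09 and 0.223 for PPAR gamma genes, and -0.09 and 0.504 for gluconeogenesis. They were 0.03 and 0.761 for glycolysis, and -0.04 and 0.504 for oxidative phosphorylation. For receptors of bile acids and xenobiotics they were -0.19 and 0.138 for bile acid receptor targets, and 0.09 and 0.103 for PXR and CAR targets. GPBAR1, which encodes a bile acid receptor at the cell surface, had a late effect of 0.04 ± 0.11 (adjusted p = 0.899). For growth and death they were -0.12 and 0.103 for G2/M genes, 0.02 and 0.384 for CDK inhibitors, -0.09 and 0.239 for p53 targets, and 0.03 and 0.504 for apoptosis regulators. They were 0.07 and 0.485 for ribosome biogenesis and MYC targets, 0.01 and 0.384 for ribosomal proteins, and -0.04 and 0.126 for core histones, whose copies are near-identical. CDKN1A, the cell cycle inhibitor p21, had -0.07 ± 0.11, MYC 0.39 ± 0.11 and EGR1, an immediate early transcription factor, 0.18 ± 0.14. For signalling they were -0.04 and 0.504 for MAPK feedback regulators, whose test pointed up and in which DUSP1 (0.72 ± 0.14) passed when adjusted over the list alone. They were -0.06 and 0.323 for cAMP response genes, whose test also pointed up. They were 0.11 and 0.217 for hypoxia genes, -0.07 and 0.217 for interferon-stimulated genes, 0.02 and 0.761 for TGF beta and matrix genes, and -0.10 and 0.761 for circadian clock genes. For liver identity they were 0.02 and 0.761 for acute phase proteins, -0.05 and 0.217 for hepatocyte genes and -0.19 and 0.155 for biliary epithelial markers. Of the markers of other cell types, 4 fibroblast, 3 endothelial and 4 leukocyte genes passed the detection filter, too few for a set test, and their late effects lay between -0.36 (PDGFRB) and 0.29 (KDR).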

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

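The list test on the difference between late and early effects was chosen after the data were seen, as were the tests of a single pair of arrays, of compressed differences at 12 h and of noise specific to the 12 h arrays. The tests of normalization, of the 12 h vehicle array and of dim genes were set down before their results were seen.

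For 6 lists the late effect differed from the early effect in the set test with the preset correlation. The NRF2 list (adjusted p = 7.74e-08), the endoplasmic reticulum list (0.00087), the ATF4 list (0.00993) and the immediate early list (0.0187) were higher at the late times, and the WNT list (0.00087) and the G1/S list (0.00993) were lower. With an estimated correlation none of the 6 passed, with adjusted p-values from 0.668 to 0.859.

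The rise of the NRF2 list at 3 to 12 h was weighed against technical explanations. Normalization or background correction as the whole cause would bring its median late effect of 0.375 below 0.188 under another scaling, and the lowest of the 3 other scalings gave 0.291. Of these 3, quantile normalization without background correction and the authors' values are nearly the same data, and both gave 0.319. One pair of arrays as the cause would bring the median to 0.1 or below without that pair, and the lowest value, without the 12 h pair, was 0.198, where random lists of matched expression rarely exceeded 0.0375. What stays open is a difference between single dishes or hybridisations that recurs at the late times, since each agent and time was measured once. A response of the cells to obacunone that builds up with time is the explanation the design names, and as a hypothesis it may account for the pattern.

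The return of the cholesterol list to the vehicle level at 12 h was weighed in the same way. A 12 h vehicle array out of line would put the list's level there at least 0.4 above the other vehicle arrays, and it lay at -0.125 from their mean. Differences that are compressed at 12 h on the whole would give a smaller spread than at 6 h, and the ratio of the standard deviations was 1.25. The level of the list on the obacunone arrays, relative to the vehicle mean, was 0.526 at 3 h, 0.673 at 6 h and -0.274 at 12 h. A transient response may account for this as a hypothesis, with 1 array behind the return.

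The number of 2-fold differences, largest at 12 h, was weighed against noise. Dim genes made up 38.8% of the 116 genes at 12 h, between the bounds set beforehand for and against noise of dim genes, so this test left it undecided. The same share was 90.9% at 0.5 h and at 1 h. Noise specific to the 12 h arrays would leave their differences unrelated to those at 6 h, measured on other arrays, and the correlation across genes was 0.31, above the highest of 0.08 among pairs with an early time. The same early pairs also reached -0.20, for 1 and 12 h. In size, their spread is thus wider than 0.08 alone would show, and noise of the 12 h arrays is not excluded. A growing response remains a hypothesis.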

How the results depend on the processing

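Alternatives marked as added (the intensity filter and the test of all rows) were chosen after the data were seen. The direction of the 11 late lists and of the 12 lists of the mean effect held under every alternative run, and 290 list calls under them were kept. The 55 list calls lost include 23 with an estimated correlation and 11 without the 12 h pair. Among the tested genes named, 86 values crossed into passing, 6 fell out, 13 turned sign and 2539 did none of these, none of the 13 with a passing effect. These tallies count the authors' values and quantile normalization without background correction separately, although they are nearly the same data. The number of late genes moved from 1 to 58 (quantile without background correction, and the authors' values), 7 (median centring), 0 (no detection filter), 19 (detected on all 11 arrays), 72 (variance prior with a trend), 2 (late from 6 h) and 0 (all rows, added). It ranged from 0 to 9 with pairs left out. The DNAJB9 call held in 8 of 14 alternatives, with adjusted p from 0.00017 to 0.265, and its effect stayed between 1.20 and 1.48. For late minus early the count went from 0 to 1 without background correction, with the authors' values and with the variance trend, and for the vehicle trend from 0 to 1 without background correction and with the authors' values. The late and mean list counts fell from 11 and 12 to 0 and 0 with an estimated correlation, and the mean list count ranged from 4 to 12 with pairs left out. The NRF2 median late effect stayed between 0.20 and 0.50. The counts of 2-fold genes from 0.5 to 12 h went from 22, 33, 18, 50 and 116 to 0, 1, 4, 10 and 23 without background correction and with the authors' values, which compresses differences of dim genes by construction. They were 5, 17 and 10 at 0.5, 1 and 3 h among genes detected on all arrays, 183 at 12 h with median centring, and 377, 528, 348, 526 and 911 with a 1.5-fold rule. Late effects that turned sign were AHR (-0.0443) and CD68 (-0.0116) with median centring, PDE4D (0.00448) with late from 6 h, and, as ranges with pairs left out, AHR (-0.092 to 0.198), CDKN2B (-0.00277 to 0.198), CRY2 (-0.311 to 0.0114), PDE4D (-0.22 to 0.00448), PPARGC1A (-0.364 to 0.258), COL1A1 (-0.0798 to 0.173), CD3D (-0.0369 to 0.179, and -0.00721 without the 6 h pair), EGR1 (-0.00526 to 0.274) and GPBAR1 (-0.0168 to 0.0899). Apart from the settings that test fewer genes or use fewer arrays, the cause was not tested. The slide block was not run.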

Other observations

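The exchange test below was chosen after the data were seen, and the splits were set down before.

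Several liver and metabolic genes passed at the late times only when adjusted over lists that did not themselves pass there. SLC2A2, the hepatic glucose transporter, had -0.60 ± 0.11 (SE, n = 3 pairs) and was lower in 3 of 3 late pairs, and TAT, tyrosine aminotransferase, was not above background on the late vehicle arrays and was at least 1.55-fold higher. Both passed when adjusted over the gluconeogenesis list alone (adjusted p = 0.00482 and 0.0164). LPIN1 (0.74 ± 0.15) and ACSL1 (0.62 ± 0.12) passed upward and DGAT1 (-0.39 ± 0.11) downward within the fatty acid list. CEBPA, a transcription factor of hepatocyte identity, went from 0.11 at 0.5 h to -1.07 at 12 h, with a late effect of -0.58 ± 0.16. In the hypoxia list, KDM3A (0.75 ± 0.19) and ADM (0.40 ± 0.11) passed upward and EPO, erythropoietin (-0.76 ± 0.17), downward, so that members of this list went opposite ways. None of these passed over all genes tested.

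STK11 and C17orf99 were higher with obacunone at both early times and lower at all 3 late times. STK11 had 0.65 at 0.5 h and -0.35, -0.53 and -0.60 at 3, 6 and 12 h, and C17orf99 0.53 and 0.37 against -0.36, -0.86 and -0.77. The difference was tested and did not pass for either (adjusted p = 0.48). Among 4506 kept rows without a gene name, 476 had an unadjusted p under 0.05 for the late effect and 0 passed after adjustment.

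Other splits of the 10 arrays were fitted in the same way, 100 including the real one. For the mean effect over 5 times the real count of genes was 0, so all 100 of 100 splits gave as many by construction and the comparison says nothing about chance. The highest other count was 3. For the late effect 31 of the 100 could not be fitted and 69 could, 9 gave at least the real count of 1 gene, and the highest other was 2, so chance cannot be excluded for that count. For the late lists 3 of 69 splits gave at least the real 11 (highest other 12), and for the lists of the mean effect 2 of 100 gave at least the real 12 (highest other 12), shares of 4.3% and 2%. Many splits put both arrays of a time in 1 group and so rest on fewer pairs, so these shares do not exclude chance. Only 10 splits, the real one included, kept 1 array of each time in each group. Of these 10, 3 gave at least 11 late lists and 1 gave at least 12 lists of the mean effect. These 3 are the same 3 counted among the 69 splits. No fitted split with both arrays of a time in 1 group thus reached 11 late lists. Exchanging agents within time pairs, which keeps the pairing, makes 16 arrangements, too few for a share under 0.05. At the late lists 4 of these gave 11 or more. These 4 leave the 3 late pairs one way round and hold the same late contrast up to its sign. The 3 splits with at least 11 late lists are among these 4 arrangements. Their high counts are thus no evidence apart from the real one. The highest of the others was 6. Over all arrangements but the real one, the median was 5 late lists and the lowest 2, so mixed arrangements also called lists. For the lists of the mean effect the real arrangement alone gave 12, and the highest other was 11, with a median of 3.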
